A study of Mus musculus with 8 samples.

How the data were processed

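RNA from P1 oocytes of wild-type and Rbpms2 knockout mice was measured in 8 libraries, 4 per genotype. Per the labels' protocols, ovaries were dissociated with collagenase (2 mg/ml) and trypsin (0.25%), 5 to 10 putative primordial oocytes were picked into a tube by mouth pipette, and mRNA was amplified for 18 cycles before library preparation. The submitters' processing notes name cutadapt, HISAT2, HTSeq and the genome build GRCm38 (mm10), and their versions and the annotation release are not given in the sources used here. The growth protocol in the labels speaks of a microarray, whereas the series type and the values are those of sequencing. Amplification of few cells without molecular identifiers means that reads are not independent molecules, so floors and intervals cover counting error only.

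The deposited values are FPKM per gene and library, one table of 21959 genes, which the authors made from gene counts per the submitters' processing notes. Of these, 21851 had a symbol match and 21902 an exon length in GENCODE release M21. Multiplied by the union exon length, the FPKM values came in steps of 1 read, and 97.5% to 97.6% of values per library were whole within 0.02 reads. Depth was taken from those steps. The recovered reads served only for depths, floors, a check for duplicated libraries and an added limma-voom fit, never for the main results. No pair of libraries within a genotype agreed within sampling noise (chi-square per degree of freedom 33.6 or above, over genes with 10 or more reads).

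Genes with an FPKM of 1 or more in at least 4 libraries (11235) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an eBayes trend, genotype as the only term and Benjamini-Hochberg adjusted p under 0.05. A fold change on that scale understates the change of low genes, and fold values given as a ratio are ratios of mean FPKM. For a gene with 0 reads in every library of a group the bound used 3 reads over the group. Of 28 gene lists fixed before the data were examined, the 26 with 5 or more tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry beside it. Marker lists of 8 other cell types were compared by their mean log2(FPKM + 1) per library with exact two-sided permutation tests over 70 splits. The genes named were fixed by rule: 14 genes always, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between genotypes (predicted and clone-named genes left out), and up to 3 called members with the smallest p per list. Further list members were named after their values were seen. These were Dppa3, Dmc1, Mael, Tdrd1 and the members given only by name, direction or log2 fold change. The change of 1 list member is not reported here.

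Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, equal totals, median-of-ratios and quantile scaling, the replicate number as a block, array weights, eBayes without trend and robust eBayes, each library left out, and other set tests. After the data were seen, limma-voom, a GC correction (loess, span 0.5, per library), the GC correction with the block, and a fit without 3 libraries rich in somatic markers were added. Genome sequence properties came from the longest coding transcript per gene in GENCODE M21.

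The steps were tested on simulated data for the knockout against wild-type comparison over 10989 genes. At 2-fold 17 of 96 changed genes were called and at 4-fold 62 of 92, with 5 false calls among 84, and the 1 planted list was called. Genes were drawn independently of each other, so the list result does not show how camera behaves with correlated genes. A planted GC trend (rank correlation -0.724) was removed by the correction. It was linear in GC and equal in all knockout libraries, a form that the correction removes by design. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.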

Results

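Transcriptomes of oocytes from newborn mouse ovaries at postnatal day 1 were measured by RNA sequencing in wild-type mice and in mice lacking Rbpms2, an RNA-binding protein with an RNA recognition motif. The series title names RBPMS2 as a regulator of early oocyte development, so the comparison asks which transcripts differ when the gene is removed. Each of the 8 libraries, 4 per genotype, was made from a tube of 5 to 10 hand-picked oocytes whose RNA was amplified for 18 cycles. The reads in the listed genes, recovered from the steps of the values, numbered 8321942 to 11941359 per wild-type library and 9564416 to 14542893 per knockout library. The labels do not say which tubes came from separate animals, so p-values measure the spread between tubes, which may be technical.

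Rbpms2 RNA was lower in every knockout library than in every wild-type library. The gene (ENSMUSG00000032387) lies on chromosome 9 from 65629648 to 65660528 in GRCm38. Its level was 168.5 ± 32.4 FPKM (SD, n = 4) in wild type and 42.5 ± 11.5 FPKM (SD, n = 4) in knockout, 3.96-fold lower. The 4 wild-type libraries had 158.1, 167.4, 135.8 and 212.8 FPKM and the 4 knockout libraries 38.4, 58.3, 31.0 and 42.5 FPKM. On the log2(FPKM + 1) scale the change was -1.98 with a standard error of 0.22 (limma adjusted p = 7.26e-05, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow). The labels do not state which part of the gene was deleted, and RNA from the rest of the locus would still be counted. Its paralog Rbpms had 11.7 ± 2.19 FPKM (SD, n = 4) in wild type and 5.25 ± 3.35 FPKM (SD, n = 4) in knockout (limma adjusted p = 0.0564). Rbpms was thus not called, though its libraries did not overlap between the genotypes. Wild-type libraries had 9.86 to 14.63 FPKM, and knockout replicates 1 to 4 had 5.92, 6.02, 8.52 and 0.56 FPKM.

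The 2 genotypes formed separate groups of libraries. Pearson correlations of log2(FPKM + 1) over 11235 genes were 0.888 to 0.959 among wild-type libraries, 0.845 to 0.928 among knockout libraries and 0.624 to 0.744 between genotypes. The leading principal component held 64.3% of the variance.

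Genes of the egg coat and of the maternal store were lower in knockout oocytes, several of them at or near 0. All 25 tested members of the fixed list of zona pellucida, oocyte-secreted and maternal-effect genes fell, and 25 also fell when adjusted over the list alone. Padi6 (ENSMUSG00000040935, chromosome 4, 140727355 to 140742643), which is needed for the cytoplasmic lattices of the oocyte, went from 1284 ± 514.5 FPKM (SD, n = 4) to 0.0378 ± 0.0588 FPKM (SD, n = 4), with 4 reads over the knockout libraries against 128123 over the wild-type ones. Zp3 (ENSMUSG00000004948, chromosome 5, 135980099 to 135988624), a glycoprotein of the zona pellucida, went from 723.9 ± 322.6 to 0.151 ± 0.21 FPKM (SD, n = 4 each). Zp1 and Zp2, which encode other proteins of that coat, fell with log2 fold changes of -7.67 and -8.94. Gdf9, a growth factor secreted by oocytes, fell from 230.8 ± 105.4 to 0.355 ± 0.429 FPKM (SD, n = 4 each), and the histone chaperone gene Npm2 from 432.8 ± 181.2 to 1.39 ± 0.813 FPKM (SD, n = 4 each). Dppa3, a maternal factor that protects DNA methylation in the zygote, was still at 135.5 ± 180.5 FPKM (SD, n = 4) in knockout, against 3027 ± 601.4 FPKM (SD, n = 4). The median log2 fold change of the list was -5.32 on the log2(FPKM + 1) scale, -7.77 with a pseudocount of 0.1 and -4.33 with a pseudocount of 5. It was -7.37 with the 6 members that had 0 reads in every knockout library set at their bound. That bound is a ratio without a pseudocount, while the other members kept theirs. The value of -7.37 thus mixes scales and is not a bound for the list. The list was shifted down by camera with a preset correlation of 0.01 (adjusted p = 2.12e-19), with adjusted p = 0.226 with an estimated correlation.

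**Figure D1:**
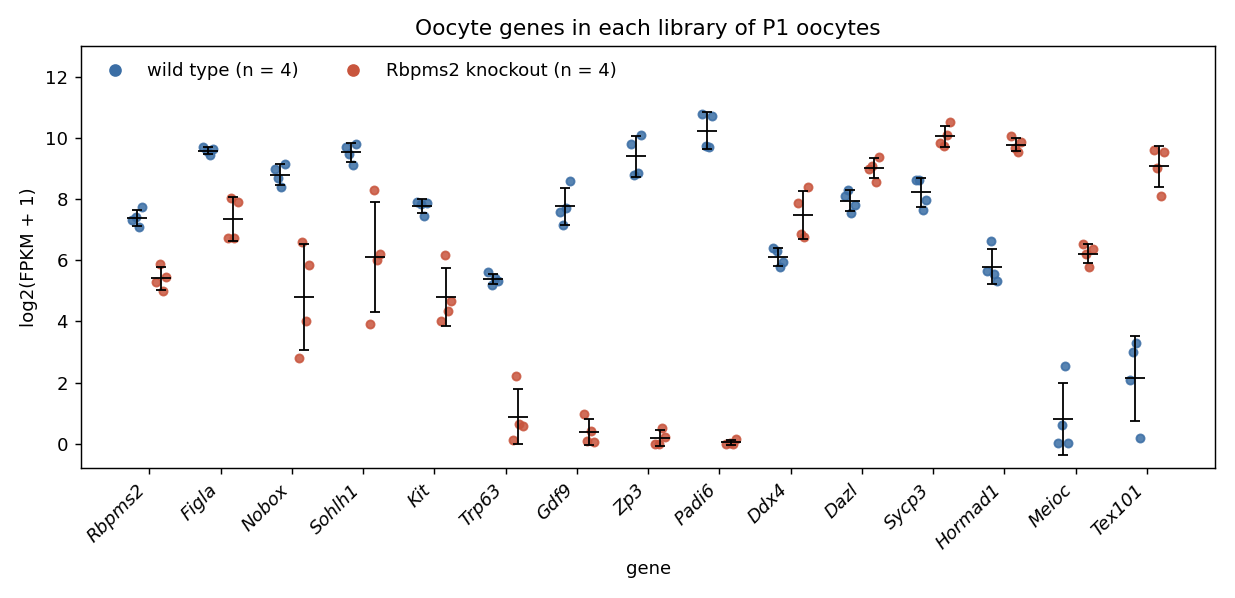
Level of 15 genes in each library as log2(FPKM + 1), wild type in blue and Rbpms2 knockout in red, with the mean and SD of 4 libraries in black. Zp3 and Padi6 lie near 0 in the knockout libraries, while Hormad1 and Tex101 are higher there than in wild type.

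Most transcription factors that drive oocyte genes were lower as well. Of 14 tested members of that list, 9 fell and 1 rose. Figla (chromosome 6, 86016171 to 86020996), which activates the zona pellucida genes, fell from 764.5 ± 55.9 to 177.7 ± 85.1 FPKM (SD, n = 4 each), and Nobox (chromosome 6, 43303674 to 43309554) from 452.2 ± 102.7 to 43.4 ± 41.5 FPKM (SD, n = 4 each). Lhx8, Sohlh1 and Foxo3 fell with log2 fold changes of -2.35, -3.43 and -2.60, and Stat3 and Ybx2 with -1.84 and -2.04. Tbpl2, an oocyte-specific relative of the TATA-binding protein, had 51.9 ± 23.3 FPKM (SD, n = 4) in wild type and 0 reads in every knockout library, at least 1139-fold lower against a floor of 3 reads over the group. The member that rose was Sub1, by a log2 fold change of 0.52, and its call ended when each library's trend against GC content was removed (the GC correction) and when any 1 library was left out. Sohlh2, Taf4b, Yy1 and Zfp322a did not pass the test. The list as a whole did not pass camera (adjusted p = 0.0627, and adjusted p = 0.835 with an estimated correlation), though it did without knockout replicate 1 (adjusted p = 0.0486) or 4 (adjusted p = 0.0318), without a filter (adjusted p = 0.0468), with quantile scaling (adjusted p = 0.0293) and after the GC correction (adjusted p = 0.0157).

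Meiotic prophase genes moved the other way. Of 37 tested members, 26 rose, 3 fell and 8 did not pass, and 27 rose and 3 fell when adjusted over the list alone. Hormad1 (ENSMUSG00000028109, chromosome 3, 95559677 to 95587671), which marks unsynapsed chromosome axes, rose from 58.1 ± 26.8 to 884.1 ± 134.8 FPKM (SD, n = 4 each). Sycp3 (chromosome 10, 88459569 to 88473236), a component of the chromosome axis, rose from 308.4 ± 99.4 to 1077 ± 270.1 FPKM (SD, n = 4 each), and Sycp2 rose 17.9-fold. Meiob, which acts in recombination, rose 24.7-fold, and the recombinase gene Dmc1 rose 16.1-fold. Meioc, which is needed to enter and hold meiotic prophase, rose from 1.34 ± 2.3 to 74.7 ± 15.7 FPKM (SD, n = 4 each). Rec114 and Syce2 fell with log2 fold changes of -0.74 and -0.67, though of the 3 members 1 stayed called lower after median-of-ratios scaling, 1 without wild-type replicate 4 or knockout replicate 3, and 2 without any other library. The list was shifted up by camera (adjusted p = 1.79e-10, and adjusted p = 0.623 with an estimated correlation). Its median log2 fold change was 1.65, and 1.21 after the GC correction, with 24 members higher and 2 lower. The fold values of single members given here are without that correction.

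Germ cell and piRNA pathway genes split, with 9 of 24 tested members higher and 6 lower (camera adjusted p = 0.436). Ddx4, a helicase gene used as a germ cell marker, rose from 69.0 ± 14.4 to 196.7 ± 106.8 FPKM (SD, n = 4 each), and Mael rose 2.5-fold. Dazl rose from 249.9 ± 57.4 to 520.7 ± 114.2 FPKM (SD, n = 4 each), but its log2 fold change went from 1.06 to 0.19 (limma adjusted p = 0.515) after the GC correction. Tex101 (ENSMUSG00000062773, chromosome 7, 24668007 to 24676675), a germ cell surface protein, rose from 4.79 ± 3.88 to 574.6 ± 228.6 FPKM (SD, n = 4 each). Kit, the receptor through which oocytes respond to KIT ligand, fell 6.79-fold, with 15.1, 70.4, 19.3 and 24.2 FPKM in knockout replicates 1 to 4. Tdrd1 and Tdrd5 fell with log2 fold changes of -2.44 and -2.17.

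Genes for DNA methylation and chromatin mostly fell, with 15 of 24 tested members lower and 2 higher. Kdm1b, a histone demethylase needed for maternal imprints, fell 12.4-fold, Uhrf1 7.38-fold and Dnmt3b 17.6-fold. Camera gave adjusted p = 0.0383 for this list, adjusted p = 0.623 with an estimated correlation, and adjusted p = 0.0539 without knockout replicate 3. Among pluripotency and primordial germ cell genes, 5 of 12 tested members fell and 3 rose. Pou5f1, Lin28a and Tcl1 fell with log2 fold changes of -2.97, -4.18 and -5.51, whereas Dppa4, Alpl and Zfp42 rose (camera adjusted p = 0.577). Of 38 tested genes for RNA binding and translational control, 11 rose and 12 fell, with Fmr1 3.96-fold higher and Elavl2 4.27-fold lower (camera adjusted p = 0.674). In that list 5 members were higher and 14 lower after the GC correction, with the median log2 fold change at -0.33 against 0.10, and 6 and 8 without wild-type replicate 4.

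**Figure D2:**
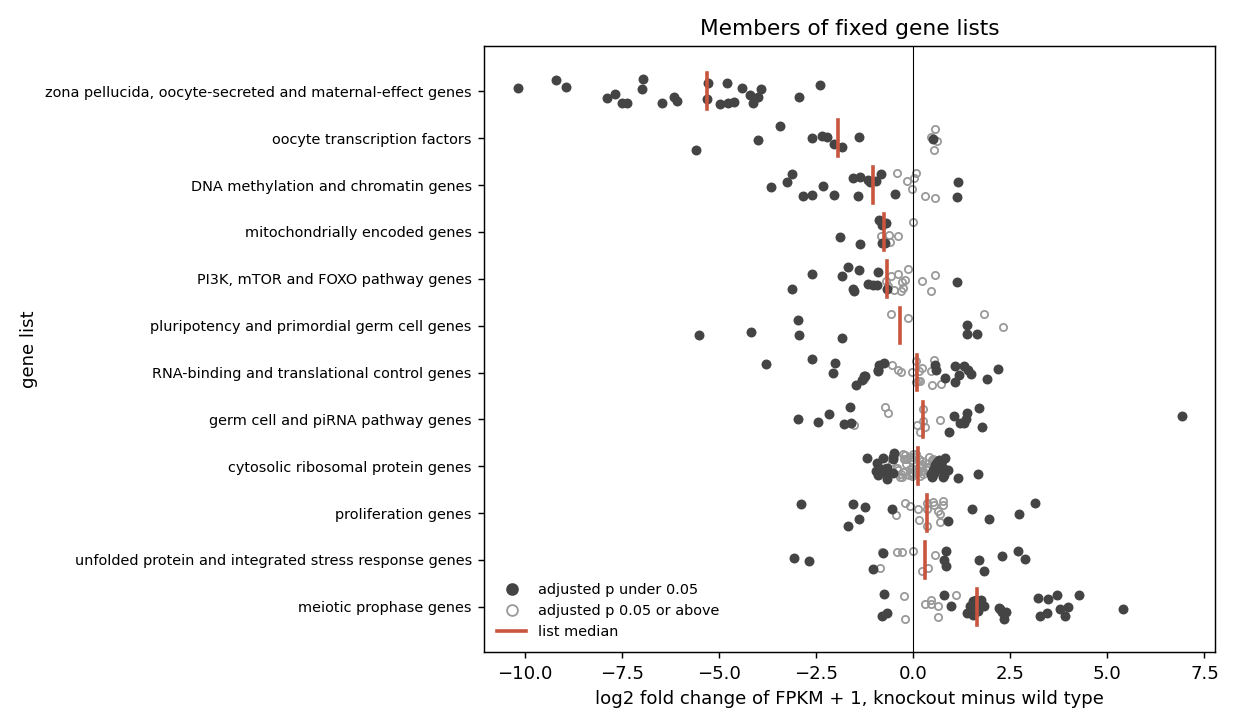
Log2 fold change of FPKM + 1, knockout minus wild type, for each tested member of 12 gene lists, with filled points at adjusted p under 0.05, open points otherwise and a red bar at the list median. The zona pellucida list has its median at -5.32 and the meiotic prophase list at 1.65.

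Survival and growth pathways also held changed members, where 43.4% of all tested genes were called. The share called was below that in the DNA damage, ribosomal protein, nuclear oxidative phosphorylation and proliferation lists. The Golgi, autophagy, BMP, glycolysis and cholesterol lists lay below it as well. It was above that in the PI3K, mitochondrial and stress response lists. Trp63, whose protein guards oocyte genome quality, fell from 40.9 ± 5.22 to 1.19 ± 1.63 FPKM (SD, n = 4 each). Chek2 fell 4.58-fold, with 2.25, 2.38, 7.19 and 2.30 FPKM in knockout replicates 1 to 4, and Mdm2 rose 3.04-fold. These genes are in a list of DNA damage and apoptosis genes where 5 of 30 members fell and 2 rose (1 rose without wild-type replicate 3 or 4 or knockout replicate 2, and 4 without knockout replicate 4). In the PI3K, mTOR and FOXO list 12 of 26 tested members fell and 1 rose, with Akt2 and Rptor 2.84-fold and 4.47-fold lower (camera adjusted p = 0.0627, but adjusted p = 0.0315 without wild-type replicate 1, adjusted p = 0.0153 without a filter and adjusted p = 0.0360 after the GC correction, and with all libraries adjusted p = 0.881 with an estimated correlation). Mitochondrially encoded genes fell in 7 of 12 cases (camera adjusted p = 0.0627), and mt-Nd3 fell by 1.89 on the log2 scale. After the GC correction 11 were lower, with a median log2 fold change of -1.55 against -0.75 (camera adjusted p = 0.000147, and without the GC correction adjusted p = 0.881 with an estimated correlation). Without one library the number lower went from 4 (wild-type replicate 3 or 4, knockout replicate 1 or 4) to 10 (wild-type replicate 1, camera adjusted p = 0.0163), and it was 2 without a filter (camera adjusted p = 0.0266). Of the cytosolic ribosomal protein genes 18 of 79 were higher and 13 lower (camera adjusted p = 0.188, and adjusted p = 0.881 with an estimated correlation). This split was 27 and 9 after median-of-ratios scaling, 20 and 3 after the GC correction (camera adjusted p = 0.00169, upward) and 12 and 15 without knockout replicate 3, and 6 to 8 were lower without wild-type replicate 2, 3 or 4 or knockout replicate 1 or 4. Nuclear oxidative phosphorylation genes went both ways (13 of 75 higher and 19 lower, 6 and 17 without wild-type replicate 4, 8 and 17 without knockout replicate 1), as did proliferation genes (5 of 26 higher and 6 lower, 10 and 5 without knockout replicate 3) and unfolded protein and stress response genes (8 of 20 higher and 4 lower, with 2 lower after the GC correction and without wild-type replicate 1, 2 or 4 or knockout replicate 1). Hspa5, the chaperone of the endoplasmic reticulum, rose 7.57-fold. Top2a rose 9.5-fold and Ube2c fell 7.54-fold. Golgi genes (6 of 26 higher, 3 lower, and 1 lower without wild-type replicate 2 or 4 or knockout replicate 1 or 2), autophagy and lysosome genes (4 of 21 higher, 3 lower), BMP and TGF-beta genes (3 of 20 higher, 5 lower, with 3 lower without wild-type replicate 3 or 4 or knockout replicate 1 or 4 and 5 higher without knockout replicate 1), glycolysis genes (3 of 14 lower) and cholesterol synthesis genes (2 of 20 higher, 6 lower) did not pass camera. Ldhb fell 16.3-fold, with 9.26, 75.2, 225.8 and 12.3 FPKM in knockout replicates 1 to 4, and Mvd fell 12.9-fold.

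Over all genes, 1991 were higher and 2880 lower in knockout at a limma adjusted p under 0.05, out of 11235 tested. By 2-fold or more on the log2(FPKM + 1) scale, 1422 were higher and 2313 lower, against 801 and 1233 with a pseudocount of 5. In 4161 of the 4871 called genes the libraries of the 2 genotypes did not overlap. Among all tested genes 39.9% did not overlap, where chance gives 2.86%. The genes with the largest rises were Tex101, H2bfm, Ccnb3, Ly6k, Dmrtc2, Lypd4, Magea5, Adad1, Magea10 and Meioc, with log2 fold changes from 6.92 to 5.41. H2bfm, Ccnb3, Magea5 and Magea10 lie on the X chromosome. H2bfm had 0 reads in every wild-type library and 94.7 ± 19.9 FPKM (SD, n = 4) in knockout, at least 1283-fold higher. Magea5 and Magea10 belong to a family that holds near-identical genes, whose reads could be assigned to the wrong copy. Magea10 (from 72381870) lies apart from Magea5 (from 155053061), and how alike their sequences are was not examined. The largest falls were in Padi6, Zp3, Zp2, Elobl, Nlrp14, Zp1, Npm2, Gdf9, Cox4i2 and Noto, with log2 fold changes from -10.18 to -7.13. Elobl and Noto had 0 reads in every knockout library and were at least 3400-fold and 3888-fold lower. Transcript GC content moved with genotype: the median log2 fold change was 0.52 in the tenth of genes lowest in GC and -0.87 in the tenth highest.

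Markers of other ovarian cells varied between tubes of both genotypes. The exact permutation test of the list means (n = 4 against 4) called 0 of the 8 marker lists, with 0 at an unadjusted p under 0.05 and 0 called from the share of the library total. Its smallest possible p is 0.0286, so after Benjamini-Hochberg correction over 8 lists fewer than 5 lists cannot pass, and the test decides nothing about a single list. Endothelial and immune cell markers had the second smallest possible p (0.0571, adjusted p = 0.228), with means of 0.50 ± 0.14 and 0.59 ± 0.35 in wild type against 1.43 ± 1.56 and 1.97 ± 1.40 in knockout (SD, n = 4 each). Knockout replicate 3 had the highest mean log2(FPKM + 1) of granulosa cell markers (3.54) and immune cell markers (3.96), and with replicate 2 of stromal markers (4.71 and 4.68). Endothelial markers stood at 3.77 in knockout replicate 1 and at 0.71 or below in the other libraries. Erythroid markers were highest in wild-type replicate 3 (4.66). In camera none of the 6 marker lists with enough tested members passed in the main fit, with the smallest adjusted p for immune cell markers (0.0627). Immune cell markers did pass, upward in knockout, without knockout replicate 1 (adjusted p = 0.0186) or 4 (adjusted p = 0.0389), without a filter (adjusted p = 0.0406) and after the GC correction (adjusted p = 0.0211), and stromal markers without knockout replicate 1 (adjusted p = 0.0186) or 4 (adjusted p = 0.0318). With the replicate block, immune (camera adjusted p = 0.0134) and stromal markers (adjusted p = 0.0396) passed upward. With the GC correction and the block, immune (adjusted p = 0.00261), stromal (adjusted p = 0.0157) and granulosa cell markers (adjusted p = 0.00364) did. In the main fit the immune, stromal and granulosa lists each had adjusted p = 0.881 with an estimated correlation. Single markers passed in both directions: Mrc1, Lyz2 and Krt18 were higher in knockout, and Lrrn4, Cnn1 and Nr0b1 lower. Fdx1, from the steroidogenic list, had a log2 fold change of 0.74. The calls of Lyz2, Krt18, Fdx1, Atf3 and Dusp1 ended under some alternative settings. Without wild-type replicate 3 and knockout replicates 2 and 3, chosen after the marker levels were seen, 2007 genes were higher and 2955 lower, and 9 glycolysis genes were lower.

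Immediate-early and heat-shock genes overlapped between the genotypes, with mean log2(FPKM + 1) of 1.73, 2.21, 3.97 and 2.93 in wild-type replicates 1 to 4 and 4.06, 4.96, 5.51 and 1.96 in knockout replicates 1 to 4. The highest level in wild type (replicate 3) and the 2 highest in knockout (replicates 2 and 3) were those of the 3 libraries richest in somatic markers, whose stromal markers stood at 3.15, 4.68 and 4.71. Of 18 tested members Fos, Atf3, Dusp1 and Ier3 rose and Hsph1 fell (camera adjusted p = 0.0564, adjusted p = 0.881 with an estimated correlation, and fry adjusted p = 0.430). Without knockout replicate 4 the median log2 fold change was 2.24 against 1.24, and 13 members were higher (camera adjusted p = 9.99e-05). The list also passed camera without wild-type replicate 3 (adjusted p = 0.0138) or 4 (adjusted p = 0.0449), without knockout replicate 1 (adjusted p = 0.0332) and after the GC correction (adjusted p = 0.00267), and all of these camera values rest on the preset correlation. Only 1 member was higher without knockout replicate 2, with voom or without a filter, and 2 without wild-type replicate 1.

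**Figure D3:**
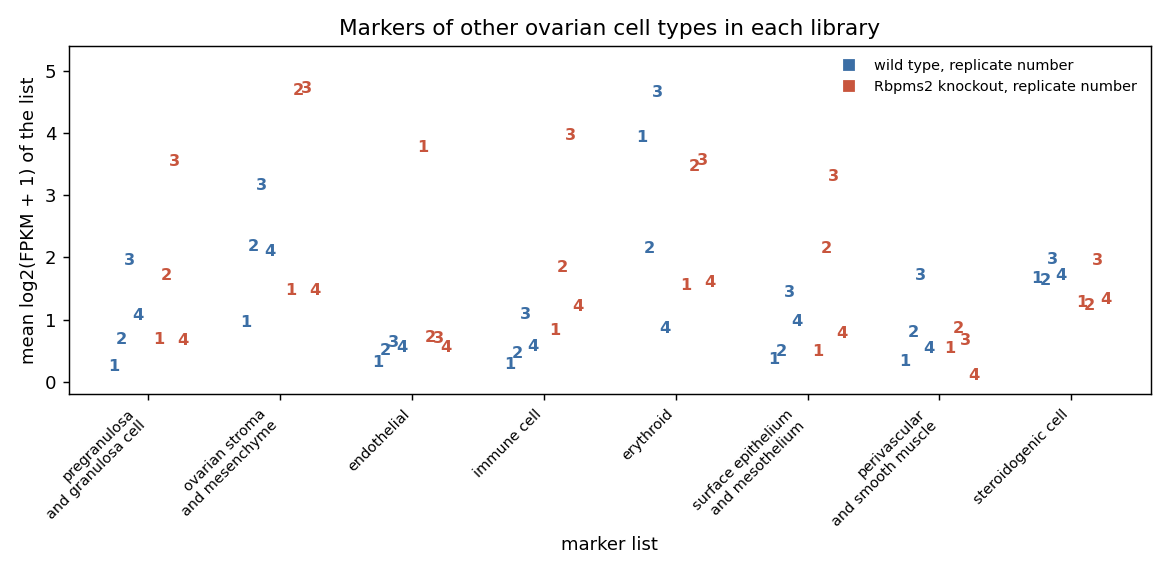
Mean log2(FPKM + 1) of 8 lists of markers of other ovarian cell types, where each digit is the replicate number of a library, blue for wild type and red for Rbpms2 knockout. Knockout replicate 1 has the endothelial level of 3.77, and knockout replicate 3 the immune level of 3.96.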

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

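Tests of fewer oocytes, of fewer somatic cells, of GC content on the X chromosome and of an equal rise along the X chromosome were chosen only after the result was seen, as were the GC correction and the fit without 3 libraries.

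Single libraries stood far from the other 3 of their genotype in 18 of 246 groups tested, where chance gives about 1 in 20 for normally spread values. For Lypd4, Magea10, Lyz2, Krt18, Zp1 and Zp2 the other 3 libraries stood at 0, so any reads in a single library were flagged. That rate does not hold for them, and an excess over chance is not shown. All values are log2(FPKM + 1). Wild-type replicate 3 was low in Kit (7.43), Ube2c (8.23) and Gpi1 (5.18), and high in mt-Nd5 (10.82), Magea10 (1.24), Lyz2 (0.54) and Krt18 (1.96). Wild-type replicate 2 was high in Ly6k (3.37) and Magea5 (2.04), and wild-type replicate 1 in Lypd4 (1.1). Knockout replicate 3 was low in Magea5 (5.3) and high in Chek2 (3.03) and in the mean of steroidogenic markers (1.95). Knockout replicate 1 was high in Zp1 (0.52) and in the mean of endothelial markers (3.77), and low in Dnmt3b (0.02). Knockout replicate 4 was high in Zp2 (0.97), and knockout replicate 2 in Lin28a (1.81).

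The fall of the zona pellucida and maternal-effect genes was weighed against 3 technical explanations. Fewer oocytes per knockout tube would lower all oocyte transcripts, yet the mean log2 fold change of the meiotic prophase list was 1.81. Its standard error of 0.254 is over list members, which come from the same libraries and are not independent replicates. The rise of that list was already known when this comparison was chosen, so the outcome was not open. After the GC correction 25 of the 25 members stayed lower, which argues against GC bias as the whole cause. Without the 3 libraries rich in somatic markers 25 of 25 did, which argues against carry-over in those libraries as the whole cause. Knockout replicate 1 (endothelial markers at 3.77) and wild-type replicate 1 (erythroid markers at 3.93) stayed in that fit, so carry-over there was not tested. An effect of the genotype stays open as a hypothesis, and no later or earlier age was measured that would show a delay.

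The rise of meiotic prophase genes was weighed in the same way. Fewer somatic cells in knockout tubes would raise all oocyte transcripts, yet the mean log2 fold change of the zona pellucida list was -5.88. Its standard error of 0.399 is likewise over list members and not over libraries. The fall of that list was also known when this comparison was chosen. Of 26 members called higher, 23 stayed higher after the GC correction and 26 without the 3 libraries. These values argue against fewer somatic cells, GC bias and carry-over in those 3 libraries as the whole cause. Carry-over in the libraries kept was not tested, and an effect of the genotype stays open as a hypothesis found and tested on the same data.

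X-linked genes were higher in knockout more often than autosomal ones, with 180 of 467 (38.5%) against 1809 of 10741 (16.8%, Fisher's exact test across genes, p = 1.5e-27), and genes are not independent replicates. Per library, the mean log2(FPKM + 1) of X-linked minus autosomal genes was -0.33 to -0.084 in wild type and 0.58 to 0.774 in knockout. The exact two-sided permutation test over libraries gave p = 0.0286, its smallest possible value. These library values had no GC correction and kept the multicopy families. After the GC correction the shares were 31.0% and 14.7%, and without multicopy families they were 32.0% and 16.8%, so neither low GC content nor shared reads accounts for the whole excess. An equal rise of all X-linked genes, multicopy families included, is argued against. The 25th percentile of GC-corrected log2 fold changes lay 0.15 above the autosomal one and the 75th lay 0.83 above. The bootstrap standard error of the 25th shift minus 50% of the 75th was 0.0756. These percentiles held the 170 genes of multicopy families and were not recomputed without them. An equal rise of the remaining X-linked genes was therefore not tested. A broad but uneven rise stays open, since the GC-corrected median was 0.22 on X against -0.11 on autosomes and 15.8% of X-linked against 26.0% of autosomal genes were called lower (Fisher's exact test across genes, p = 3.1e-07), and no biological cause was tested.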

How the results depend on the processing

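The voom, GC-corrected and 3-library fits were chosen after seeing the data. The log2 fold change of Rbpms2 lay between -2.14 and -1.60 and stayed called in every fit. Without one library, 1516 to 1949 genes were higher and 2393 to 3011 lower. With pseudocount 5 the genes changed by 2-fold or more were 801 higher and 1233 lower, since a larger pseudocount shrinks fold changes. The number of lists called by camera with its preset correlation moved, mostly by over 1.5 times: 5 with pseudocount 5, 7 without a filter, 9 with the GC correction, 11 with the GC correction and replicate block, and 2 to 7 without one library (5 without wild-type replicate 1, 7 without knockout replicate 1 or 4, 2 without knockout replicate 3), and the cause was not tested. With an estimated correlation camera called 0 lists, and fry, which asks another question of each list, called 11. The numbers did not pair the libraries (deviations of same-numbered libraries correlated by 0.185, 0.016, 0.361 and -0.053, and in 1 of 4 numbers both libraries correlated best with their own). The replicate block gave 2113 higher, 2921 lower and 8 lists, adding the PI3K, mitochondrial, immediate-early, stromal and immune lists. Median-of-ratios and quantile scaling moved the median log2 fold change of all genes from -0.12 to 0.003 and 0.043, and gave 2313 and 2503 higher and 2493 and 2511 lower genes. Of the other genes taken by the naming rule 38 calls were lost over all settings, and 5 gained, all in Rbpms, and no direction reversed. Among the 38, Dazl lost its call after the GC correction, Krt18, Pgam1 and Fdx1 in several single-library fits, and Atf3, Dusp1, Lyz2 and Krt18 with voom. Members named outside that rule are not in these counts, and some of them lost calls as well, Sub1 among them. The DNA methylation list lost its call with pseudocount 0.1 (adjusted p = 0.0618), without knockout replicate 3 (0.0539) and without the 3 libraries (0.0982). Genes changed by 2-fold were recovered in 17.7% of simulated cases, where few genes were changed and 84 of 10989 were called. The real fit called 4871 of 11235, so its adjusted p threshold was reached more easily. The simulated share therefore does not give the share of changes missed in the real fit.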

Other observations

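The GC trend test on ribosomal protein genes and the CAC test were planned before their results were seen, and the gene families were chosen after seeing the data.

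Among 334 groups of genes sharing a symbol root, 5 were called higher more often than other genes and 1 lower (one-sided Fisher's exact tests across genes, Benjamini-Hochberg adjusted). The calls were those of the main fit and were not repeated after the GC correction, and genes of a family are not independent replicates. All 7 tested Magea genes were higher (adjusted p = 0.0016), as were 11 of 19 Rhox homeobox genes (adjusted p = 0.0082), both X-linked families whose near-identical copies can share reads. Among all X-linked genes 38.5% were called higher, and an excess of these families over that share was not tested. Of 8 Cct genes, which encode subunits of the cytosolic chaperonin, 7 were higher (adjusted p = 0.0041), and of 8 Psma genes for alpha subunits of the proteasome core 6 were (adjusted p = 0.0415), while of 9 Psmb genes for its beta subunits 1 was higher and 3 were lower. Genes named Tex, for testis-expressed, were higher in 11 of 16 cases (adjusted p = 0.0016), a name and not a shared function. Of 22 Fbxw genes 17 were lower (adjusted p = 0.000191), most of them similar copies that can share reads.

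Log2 fold change fell with transcript GC content, with a slope of -0.0695 per percentage point over all genes. Ribosomal protein genes, which are made together, had a slope of -0.0464 with a standard error of 0.0123, so GC bias of amplification or sequencing may account for part of the trend. The 4 wild-type libraries had slopes above 0 against the mean of all libraries and the 4 knockout libraries slopes below 0, so such a bias would coincide with genotype, and an effect of the genotype itself stays open.

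RBPMS proteins bind CAC motifs, so it was tested whether CAC-rich 3' UTRs mark changed transcripts. Over 10686 genes, the median GC-corrected log2 fold change differed by -0.127 between the upper and the lower quartile group of CAC per kilobase (upper minus lower, bootstrap standard error 0.0381). In a model with 3' UTR GC and length the CAC term had the same sign, -0.00614 per CAC per kilobase (standard error 0.0018). Both errors are over genes, which are not independent replicates. The size of the median difference lies between the bounds of 0.1 and 0.2 set beforehand, so the hypothesis is not decided. Single CAC trinucleotides were counted, and a signed median would not show targets that move in both directions.

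Other splits of the 8 libraries into 4 and 4 called at most 1 gene, against 4871, 1991 higher and 2880 lower for the genotypes. So 1 of 35 splits gave as many, the smallest share that 35 splits allow. Each other split puts both genotypes in both groups, so a large genotype difference widens its spread and leaves few calls. A cause shared by the tubes of a genotype, such as a shared animal, is not tested by these splits. For the number of lists called by camera chance is not excluded: 31 of 35 splits called 3 or more, and the highest other called 13, so 3 called lists are no more than other splits give. The member counts of the lists rest on the gene tests, in which other splits called at most 1 gene, with the same limit.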
